A study of Mus musculus with 10 samples.

How the data were processed

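Single-cell RNA of 10 libraries from metastatic ID8 tumours of the diaphragm (8 libraries) and omentum (2 libraries) was measured with a droplet-based kit that captures 5′ transcript ends. Per the labels' protocols, tumours were cut up and digested with collagenase and DNase, red cells were lysed, and CD45-positive cells were enriched with magnetic beads before encapsulation. The values are raw UMI counts per gene and cell as deposited by the authors, made with Cell Ranger 5.0.1 against mm10 per the submitters' processing notes. No normalization, doublet removal or cell annotation is recorded in the sources used here. Each matrix held 32285 genes, and 32158 of the gene IDs were found in the GENCODE vM21 annotation of GRCm38, from which gene positions were taken. Counting at the 5′ end is not sensitive to a short edit or to loss of an internal exon. Near-identical genes, such as Tgtp1 with Tgtp2, Gbp2 with Gbp2b and Hspa1a with Hspa1b, can share reads, so their counts are uncertain.

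Groups were taken from the tumour site, the edited gene in the cancer cells and the mouse genotype in the labels. Replicate numbers were given in deposit order and pair nothing. The Il4 knockout was tested on 3 control and 3 knockout libraries whose titles share the prefix BM1. The fourth control, which shares its prefix with the Ccl7 knockout library, entered only as an alternative and as the control of that pair. The omentum and Ccl7 pairs had 1 library per group and no test.

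Cells were kept with at least 500 UMIs, at least 200 genes and under 10% mitochondrial UMIs. Failing barcodes numbered 1130, 1740, 964 and 1122 in F8 controls 1 to 4, 1102, 653 and 1131 in the Il4 knockout libraries, 514 in the floxed littermate, 866 in the Cre-carrying library and 173 in the Ccl7 knockout library. Doublets were scored by simulation with scanpy's Scrublet (expected rate 0.08). Its automatic threshold marked too few cells, so the highest scores were removed at 0.8% per 1000 barcodes of the library, a choice made after seeing that result. This removed 749, 589, 744 and 590 cells from the controls, 793, 664 and 745 from the Il4 knockout libraries, 566 from the littermate, 356 from the Cre-carrying library and 5 from the Ccl7 knockout library. Kept cells were normalised to 10000 UMIs and log-transformed. The 2000 most variable genes over libraries, leaving out mitochondrial, ribosomal, immunoglobulin, T cell receptor, haemoglobin and sex-linked genes, gave 30 principal components, a graph of 15 shared nearest neighbours and Leiden clusters at resolution 1 (0.5 and 2 as alternatives). No batch correction was applied.

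Clusters were named "X-like" from cell type markers fixed before the data were examined, as were the gene lists, tests, named-gene rule and main alternatives. A name needed at least 3 markers detected in at least 10% of cells and raised by at least 0.5 on the log2 scale over all other cells, and the name with the largest mean rise was used. A cluster stayed unnamed when more markers of another lineage than of its own stood among its 10 leading genes, when another lineage's markers were detected at 0.6 or more of that lineage's own level, or when it was shallow (median UMIs under 1/3 of its library's) with few or no markers raised. This scoring was set after the clusters were seen. The rule for shallow clusters was tightened for 1 cluster before any comparison of groups, and fibroblast and endothelial lineages were separated in the rule after the first counts of called genes were seen, which left 1 pericyte-like cluster unnamed and moved the endothelial-like count. Raw counts were summed per class and library. Classes with at least 30 cells in each of the 6 libraries were tested, which left out NK-like and plasmacytoid dendritic-like cells.

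Sums were tested with edgeR 4.0.16 (TMM normalization, filterByExpr with a minimum count of 10, quasi-likelihood F test, two-sided, Benjamini-Hochberg adjustment over all genes of a class, threshold 0.05). Standard errors were derived from the fold change and the F statistic. The 34 fixed lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a class with at least 4 tested members, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. Differences between classes were tested with interaction terms in a model with library and class. Shares used an exact two-sided permutation test of the means over the 10 distinct splits. For pairs of single libraries, CPM per class were given with exact Poisson or binomial intervals, genes needed at least 10 counts over both libraries, and list medians of log2 ratios (pseudocount 0.5 counts) were placed among 10000 random lists of equal size matched on expression in 20 bins. Folds against 0 counts were computed against a floor of 3 counts per library. Shared controls were simulated with unchanged groups.

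Genes were named by rule. In macrophage-like cells these were the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 20 CPM and no overlap between groups (30 of 48 called genes met the conditions), in other classes 4 each way, or the 3 lowest p-values where none passed. Passing lists gave up to 4 members past the threshold, or else the 2 of highest expression. The pairs gave the 10 highest and lowest ratios in macrophage-like cells and 3 each way in classes with at least 100 cells in each library, among genes of at least 50 CPM in 1 library and 30 counts. A set of IL-4, Ccl7 and target genes was always given. Variable segments, mitochondrial genes and predicted genes were counted and not named, and a few genes that the rule chose are not reported here. Clec9a and Xcr1, Ifng, Ccz1 outside the Il4 knockout comparison, the cluster leaders and the class markers were named outside the rule, as were F13a1 and Alox5ap in epithelial/mesothelial-like cells. A comparison of the Ccl7 knockout library with the BM1 controls over called genes was set aside when its direction turned and later restored, and the positions of F8 control 4 were tabulated after the values were seen.

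Alternatives were DESeq2 1.42.0, RLE normalization, no low-count filter, each library left out, F8 control 4 added, doublets kept, stricter cells (at least 1000 UMIs and 500 genes, under 5% mitochondrial), both other resolutions, macrophage-like with monocyte-like cells, libraries thinned to 13736995 UMIs, shares of immune cells, and edgeR on cell counts. Added after seeing the data were macrophage-like cells without shallow clusters (here median UMIs under 0.5 of the library's, met by cluster 5 alone) or with the left-out clusters of macrophage markers, and T-like cells with the mixed cluster. The tests were tried on simulated data with 200 changed genes per class. In macrophage-like sums of 12687 genes, 74.0% of genes changed 2-fold and 95.9% of genes changed 4-fold were recovered, with 18 false among 186 calls, and over the 11 classes recovery ran from 23.5% to 74.2% and from 86.5% to 100%. Software was Python 3.11.15 with scanpy 1.11.5, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3. Not analysed here were T cell subtypes and receptor sequences.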

Results

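ID8 cells, a cancer line derived from mouse ovarian surface epithelium, were grown as metastatic tumours in C57BL/6J mice, and the cells of 10 tumour samples were profiled by droplet-based single-cell RNA sequencing of the 5′ ends of transcripts after enrichment for CD45, the pan-leukocyte surface protein. The cancer cells had been CRISPR-edited at F8 (coagulation factor VIII, the control target), at Il4 or at Ccl7. Diaphragm tumours comprised 4 F8 control libraries, 3 Il4 knockout libraries and 1 Ccl7 knockout library. The omentum gave 1 library from a mouse with floxed Il4ra that also carried Ms4a3-Cre, which is active in progenitors of monocytes and granulocytes, and 1 library from a floxed littermate, both with F8 control cancer cells. F8 controls 1 to 3 and all Il4 knockout libraries carried the title prefix BM1, the omentum pair BM2, and F8 control 4 and the Ccl7 knockout library BM3. The tests therefore set 3 BM1 controls against 3 BM1 knockout libraries, and the other comparisons had 1 library per group and no test. The labels do not say that the libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

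Total counts were 81429411, 46039946, 75682399 and 90913202 unique molecular identifiers (UMIs) in F8 controls 1 to 4 and 106417629, 47472445 and 63542029 in Il4 knockout libraries 1 to 3. They were 66557432 in the floxed littermate, 53693312 in the Cre-carrying library and 30507059 in the Ccl7 knockout library. After filtering, 8380, 7162, 8429 and 7455 cells were kept in the controls, 8628, 8126 and 8353 in the Il4 knockout libraries, 7593 in the littermate, 5898 in the Cre-carrying library and 737 in the Ccl7 knockout library. Median UMIs per kept cell were 4323, 2883, 4376 and 7614 in the controls, 5913, 2725 and 3194 in the Il4 knockout libraries, 3970 in the littermate, 5325.5 in the Cre-carrying library and 26091 in the Ccl7 knockout library. The last library thus held far fewer and far deeper cells than the control it is compared with. Values below are means of counts-per-million values (CPM, UMIs of a gene scaled to the total UMIs of its cell class) ± SD over 3 libraries, unless stated otherwise, and Poisson or binomial intervals on single libraries are exact 95% intervals that cover counting error only.

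The edited genes were examined first. Il4 (ENSMUSG00000000869, chromosome 11, 53602982 to 53618669, minus strand, GRCm38) was near the detection limit in every library. All kept cells together held 15, 30 and 20 Il4 UMIs in BM1 controls 1 to 3, 31 in F8 control 4 and 38, 12 and 29 in the Il4 knockout libraries, with 3 in the littermate, 2 in the Cre-carrying library and 1 in the Ccl7 knockout library. The means were 0.429 ± 0.297 CPM in BM1 controls and 0.413 ± 0.118 CPM in knockout libraries. In epithelial/mesothelial-like cells, the class that holds cancer cells, BM1 controls held 1 Il4 UMI and knockout libraries 12. Counts of 5′ ends need not fall when a short CRISPR edit disrupts a coding exon, so these values neither check nor contradict the labels. F8 (ENSMUSG00000031196, X chromosome, 75172715 to 75382615, minus strand) stood at 1.96, 3.15 and 0.772 CPM of all kept cells in BM1 controls, 0.584 in F8 control 4 and 1.04, 1.24 and 1.56 in the Il4 knockout libraries. It stood at 0.842 CPM in the littermate, 0.818 in the Cre-carrying library and 0.712 in the Ccl7 knockout library. Ccl7 (ENSMUSG00000035373, chromosome 11, 82045712 to 82047525, plus strand) stood at 8.999, 5.57 and 6.47 CPM in epithelial/mesothelial-like cells of BM1 controls, 48.2 in F8 control 4 and 7.92 (6.71 to 9.29) in the Ccl7 knockout library. It stood at 7.29, 4.74 and 11.1 CPM in the Il4 knockout libraries and at 27.6 and 37.5 CPM in the littermate and the Cre-carrying library. The Ccl7 knockout value was 0.165 times (0.139 to 0.194) that of F8 control 4 and inside the range of the BM1 controls. Macrophage-like cells held a mean of 447 CPM of Ccl7 in BM1 controls and 714 CPM in F8 control 4. The macrophage markers C1qa, C1qb and C1qc put macrophage RNA at 0.907% to 1.38% of epithelial/mesothelial-like UMIs in BM1 controls. Part of the Ccl7 in this class may thus be macrophage RNA, which was not tested for this gene. Il4ra (ENSMUSG00000030748, chromosome 7, 125552120 to 125579474, plus strand) stood at 92.8 CPM (82.6 to 104) in macrophage-like cells of the Cre-carrying library and 90.2 CPM (83.6 to 97.3) in those of the littermate, a ratio of 1.03 (0.895 to 1.18). Loss of a floxed exon need not lower counts taken at the 5′ end, so this ratio does not check the deletion either.

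The Il4 knockout comparison asked how tumour-associated cells differed when the cancer cells carried an Il4 knockout, Il4 being the cytokine that drives alternative activation of macrophages through STAT6. In macrophage-like cells of Il4 knockout tumours, genes induced by interferon-γ and genes of antigen presentation were higher by camera with its preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.143 for each of these 3 lists). Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079, minus strand), a chemokine that attracts CXCR3-bearing T cells, rose from 194 ± 36.6 to 799 ± 188 CPM. The log2 fold change was 2.10 (SE 0.19, adjusted p = 0.0354, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ctsk (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362, plus strand), the collagen-degrading protease cathepsin K, fell from 42.6 ± 22.3 to 3.43 ± 0.617 CPM, a log2 fold change of -3.55 (SE 0.44, adjusted p = 0.0427). Cluster 39, led by Ctsk and Mmp9, was left unnamed and out of these sums. It held 15, 4 and 7 cells in BM1 controls, 2, 6 and 1 in knockout libraries and 1 in F8 control 4. What it adds to Ctsk in macrophage-like sums was not tested. In all, 37 genes were higher and 11 lower of 12849 tested, with 1749 at an unadjusted p under 0.05. For all 48 the knockout and control libraries did not overlap. Chance gives that arrangement for 10% of unselected genes in a comparison of 3 with 3, but the test that called these genes favours it. Non-overlap of called genes, here and in the classes below, is therefore no separate support.

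Among the other higher genes in macrophage-like cells, the largest fold change belonged to Dnase1l3, a secreted DNase, which rose from 15.98 ± 4.71 to 83.5 ± 29.7 CPM (log2 2.45, SE 0.32). H2-M2, a non-classical MHC class I gene, rose from 10.2 ± 4.05 to 48.2 ± 13.1 CPM. The protease inhibitor gene Serpina3g rose by 1.86 on the log2 scale, the leukocyte receptor gene Slamf8 by 1.84 and Calhm6, which encodes a channel of the calcium homeostasis modulator family, by 1.60. Of the interferon-inducible GTPases, Gbp2 rose from 84.2 ± 17.2 to 215 ± 28.6 CPM, and Gbp4, Tgtp2 and Gbp3 rose by 1.43, 1.20 and 1.15. H2-DMb1, whose product helps load peptides on MHC class II, rose from 256 ± 37.3 to 531 ± 93.4 CPM. Adjusted p-values of these genes from edgeR's quasi-likelihood test lay between 0.0354 for Tgtp2 and 0.0471 for Dnase1l3. On the lower side, Emp1, an epithelial membrane protein gene, fell from 136 ± 20.5 to 55.7 ± 12.3 CPM. The glucocorticoid-responsive transcription factor gene Klf9 and Tnfsf9, which encodes the T cell costimulatory ligand 4-1BBL, each changed by -0.89. Arhgap24, a GTPase-activating protein gene, and Pde3b, a cyclic AMP phosphodiesterase gene, changed by -0.59 and -0.58 (adjusted p = 0.0490 for Pde3b, the highest of the lower genes named here).

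The fixed list of interferon-γ-induced genes had all 19 of its tested members above 0 in macrophage-like cells, with a median log2 fold change of 0.73. Of these members 6 passed over all genes and 15 adjusted over the list alone, and camera with its preset correlation gave an adjusted p = 2.9e-33 over the 34 lists tested in this class. With an estimated correlation the adjusted p = 0.143, so this call was lost. The MHC class II presentation list had 13 of 14 members above 0 (median 0.97, adjusted p = 7.5e-28, and adjusted p = 0.143 with an estimated correlation). Of this list 3 members passed over all genes, H2-DMb1, H2-DMa (0.92) and the costimulatory receptor gene Cd40 (0.81), and 11 adjusted over the list alone. The MHC class I presentation list had 13 of 14 members above 0 (median 0.56, adjusted p = 4.5e-17, and adjusted p = 0.143 with an estimated correlation), with 4 past the threshold over all genes and 10 adjusted over the list alone. Those 4 were the immunoproteasome subunit genes Psmb9 (0.81), Psmb10 (0.75) and Psmb8 (0.68) and the peptide transporter gene Tap2 (0.62). Dendritic cell maturation genes had 12 of 15 members above 0 (median 0.53, adjusted p = 2.1e-09, and adjusted p = 0.151 with an estimated correlation), again with Cd40 past the threshold over all genes and 6 members adjusted over the list alone.

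On the other side, all 17 tested lipid-associated and scar macrophage genes lay below 0 (median -0.44, adjusted p = 3.3e-10, and adjusted p = 0.236 with an estimated correlation), none passing over all genes and 3 adjusted over the list alone. Apoe and Ctsb, the members of highest expression, had log2 fold changes of -0.52 and -0.37 and did not pass. Resident macrophage genes had a median of -0.55 with 3 of 17 above 0 (adjusted p = 1.4e-04, and adjusted p = 0.515 with an estimated correlation), none passing over all genes and 1 adjusted over the list alone. The platelet factor gene Pf4 stood at 1282 CPM in controls and 604 in knockout libraries without passing (adjusted p = 0.143). Glycolysis and hypoxia genes had a median of -0.25 with 2 of 17 above 0 (adjusted p = 1.1e-04, and adjusted p = 0.680 with an estimated correlation). Oxidative phosphorylation genes had all 19 members above 0 (median 0.23, adjusted p = 9.4e-07, and adjusted p = 0.515 with an estimated correlation), and cell cycle genes all 20 (median 0.27, adjusted p = 0.00113, and adjusted p = 0.880 with an estimated correlation). Neither had a member past the threshold over all genes, and 4 and 0 members passed adjusted over the list alone. In glycolysis and hypoxia 0 members passed over all genes and 4 adjusted over the list alone, and the neutrophil granule list, with 1 of 10 above 0 (median -0.30), had an adjusted p = 0.0393, and adjusted p = 0.685 with an estimated correlation.

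Genes set in advance as readouts of IL-4 signalling did not move as a group in macrophage-like cells. The 21 tested IL-4/STAT6-induced genes had a median of -0.03 (adjusted p = 0.833), with 2 members higher and 2 lower adjusted over the list alone and none over all genes. The type I interferon list also had a median near 0 (-0.02, 18 members, adjusted p = 0.833). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand), the arginine-consuming enzyme used as a marker of alternative activation, stood at 2719 ± 748 CPM in controls and 1216 ± 263 in knockout libraries without passing (log2 -1.12, SE 0.23, adjusted p = 0.113). Spp1, which encodes osteopontin, stood at 497 ± 163 and 188 ± 21.4 CPM (adjusted p = 0.0622). Chil3, a chitinase-like gene induced by IL-4, stood at 87.4 ± 68.8 and 19.1 ± 20.2 CPM (adjusted p = 0.314), and the mannose receptor gene Mrc1 at 190 and 121 CPM (adjusted p = 0.343). Retnla (33.1 and 47.3 CPM), Cd274, which encodes the checkpoint ligand PD-L1 (101 and 129), Il4ra (79.6 and 70.3), Stat6 (57.4 and 50.6) and Ccl7 (447 and 326) did not pass either. Il13ra1 changed by -0.10 on the log2 scale without passing (adjusted p = 0.612). Il4, F8 and Ms4a3 had too few counts in these cells to be tested.

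Markers of other cell types moved with the knockout in the macrophage-like sums. Clec9a and Xcr1, markers of cross-presenting dendritic cells chosen here after their values were seen, rose from 3.19 ± 0.680 to 14.0 ± 3.90 CPM and from 1.97 ± 0.371 to 7.41 ± 1.79 CPM (log2 2.20 and 1.96, adjusted p = 0.0427 for each). Of the further dendritic cell genes Flt3 (0.36, adjusted p = 0.713) and Naaa (0.49, adjusted p = 0.113) did not pass. All 6 T cell marker genes lay above 0 in macrophage-like cells (median 0.76, adjusted p = 4.0e-04, and adjusted p = 0.515 with an estimated correlation), none passing singly by either adjustment. T cell cytotoxicity genes had a median of 0.88 (8 of 9 above 0, adjusted p = 6.0e-09, and adjusted p = 0.143 with an estimated correlation; 0 members over all genes and 4 adjusted over the list alone). T cell exhaustion genes had a median of 0.55 (10 of 11 above 0, adjusted p = 1.7e-05, and adjusted p = 0.143 with an estimated correlation; again 0 and 4). Of the 34 lists 13 passed in macrophage-like cells, 9 higher and 4 lower, while 0 passed with an estimated correlation or with fry. The largest macrophage-like cluster differed between libraries. Cluster 5, with median UMIs at 0.391 of its libraries' median, was largest in control 1, cluster 2 (led by Fcna, Cbr2 and Folr2) in controls 2 and 3 and in knockout library 2, and cluster 1 (led by Cx3cr1 and Cxcl9) in knockout libraries 1 and 3 and in F8 control 4.

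The macrophage-like call rested on which libraries entered. Without controls 1, 2 or 3 in turn, 4, 175 and 1 genes passed, and without knockout libraries 1, 2 or 3, 0, 104 and 2 genes did, with 1003 at an unadjusted p under 0.05 where 0 passed. Adding F8 control 4 to the controls left 0 genes (823 at an unadjusted p under 0.05), and of the 48 genes 19 had their F8 control 4 value within or beyond the range of the knockout libraries, 24 between the groups and 5 within or beyond the range of the BM1 controls. Cxcl9 stood at 348 CPM in that library, Dnase1l3 at 55.5, H2-M2 at 54.5, H2-DMb1 at 560 and Ctsk at 1.79. No gene passed with doublets kept (1703 at an unadjusted p under 0.05), while DESeq2 called 310, a fit without a low-count filter 201, the stricter cell filter 21 and clustering at resolutions 0.5 and 2 called 15 and 16. With monocyte-like cells included 24 passed, without cluster 5 24, and with the left-out clusters that carried macrophage markers 22. Of the genes given by size of change or as IL-4 readouts, Retnla alone changed direction in any of these settings, from 0.54 to -0.17 with F8 control 4 added, and passed in neither.

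**Figure D1:**
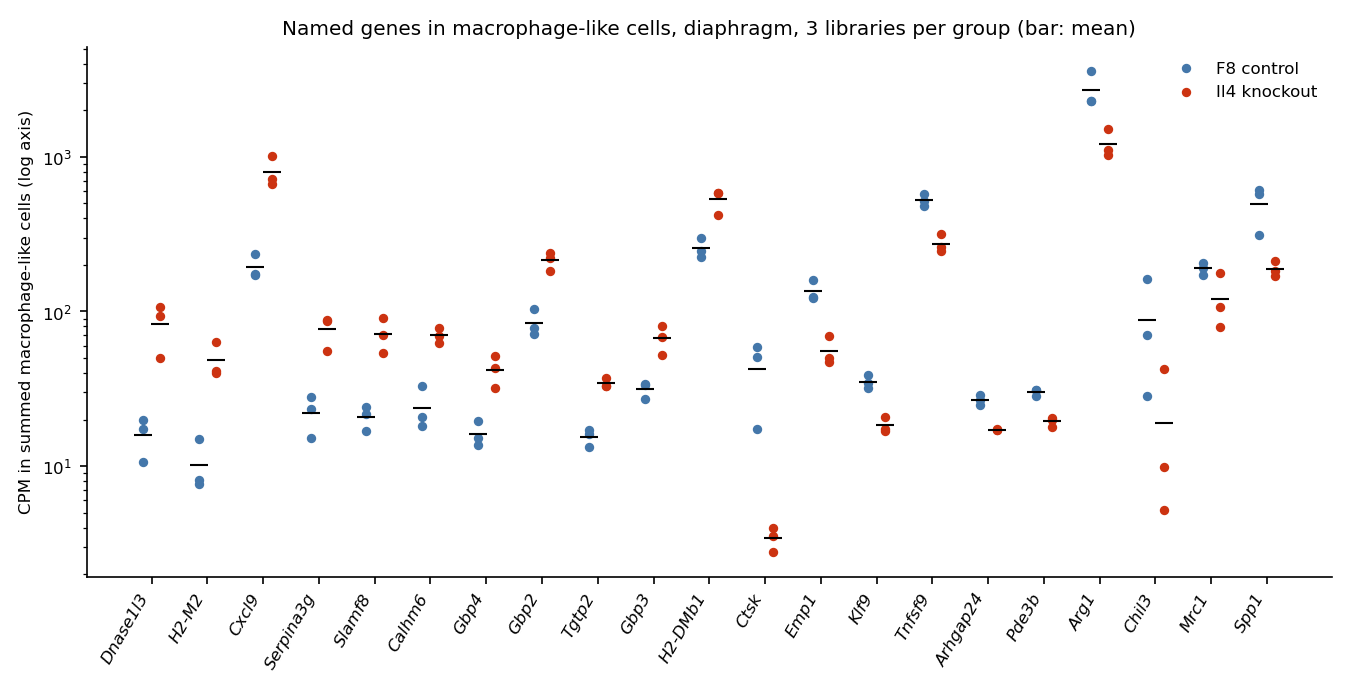
CPM (log axis) of named genes in summed macrophage-like cells of the diaphragm, with 1 point per library for 3 F8 controls (blue) and 3 Il4 knockouts (red), bars marking the means of the 3 libraries. Cxcl9 means were 194 and 799 CPM and Ctsk means 42.6 and 3.43, without overlap, whereas Chil3 and Mrc1 libraries overlapped.

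Monocyte-like cells of Il4 knockout tumours had lower Arg1. Of 7351 genes 29 were higher and 42 lower (840 at an unadjusted p under 0.05), without overlap between groups for all 71. Arg1 fell from 3333 ± 536 to 1208 ± 325 CPM (log2 -1.51, SE 0.18, adjusted p = 0.00545, edgeR's quasi-likelihood test). Ace, the angiotensin-converting enzyme gene expressed by patrolling monocytes, rose from 6.15 to 55.8 CPM (log2 3.14, adjusted p = 0.00545), and the receptor kinase gene Grk3 from 9.96 to 35.2. Ccl17, a chemokine induced by IL-4 in myeloid cells, fell from 39.9 to 7.11 CPM (log2 -2.45, adjusted p = 0.0359), the macrophage elastase gene Mmp12 from 283 to 76.1, the epidermal growth factor family ligand gene Areg from 288 to 81.5 and the metallothionein gene Mt2 from 223 to 74.7. Among the 17 lipid-associated genes (median -0.51, adjusted p = 2.2e-13, and adjusted p = 0.146 with an estimated correlation), 4 fell over all genes and 11 adjusted over the list alone, including Trem2, a lipid-sensing receptor gene (443 to 240 CPM), and the fibronectin gene Fn1 (log2 -0.82). Glycolysis and hypoxia genes (median -0.40, adjusted p = 9.0e-09, and adjusted p = 0.146 with an estimated correlation) had 4 of 16 lower over all genes, namely Bnip3, Eno1, Pgk1 and Gapdh, and 9 adjusted over the list alone. Of 16 NF-κB cytokine genes (median -0.41, adjusted p = 3.2e-08, and adjusted p = 0.270 with an estimated correlation) 3 fell, among them Cxcl1 (-1.38) and Il1a (-0.68), and 8 adjusted over the list alone. The 17 IL-4/STAT6-induced genes had a median of -0.29 (adjusted p = 6.1e-04, and adjusted p = 0.146 with an estimated correlation), with 1 member higher and 3 lower adjusted over the list alone. The interferon-γ and MHC class I lists had medians of 0.64 (adjusted p = 6.1e-07, and adjusted p = 0.337 with an estimated correlation) and 0.57 (adjusted p = 2.2e-09, and adjusted p = 0.253 with an estimated correlation). Neither held a member past the threshold over all genes, and 5 and 9 members passed adjusted over the list alone. The inducible heat shock genes Hsph1, Hspa1b and Hspa1a rose by 1.57, 1.34 and 0.98, and the dissociation stress list that holds them had a median of 0.08 (adjusted p = 0.0318, and adjusted p = 0.433 with an estimated correlation). The monocyte markers Plac8, Ly6c2 and Ms4a4c, which also served to name the class, were among the higher genes (2.01, 1.97 and 1.04). The 12 monocyte genes had a median of 0.32 (adjusted p = 7.9e-04, and adjusted p = 0.169 with an estimated correlation) and the 9 resident macrophage genes -0.40 (adjusted p = 4.1e-04, and adjusted p = 0.253 with an estimated correlation). Monocyte and macrophage markers thus moved apart in these sums, which do not separate a change within monocytes from a change in the make-up of the class. Leaving out knockout libraries 1, 2 or 3 gave 12, 35 and 16 genes, of which 10, 25 and 10 were among the 71. Leaving out control 1 or 3 gave 46 and 38, of which 37 and 32 were. Adding F8 control 4 left 0 genes (513 at an unadjusted p under 0.05). The F8 control 4 value lay within or beyond the knockout range for 45 of the 71. It lay between the groups for 20 and within or beyond the control range for 6. Ace (59.3 CPM), Ccl17 (0.989), Mmp12 (41.5) and Mt2 (72.2) were on the knockout side, Grk3 (27.7) and Areg (153) between. DESeq2 called 108, and a fit without a low-count filter 381.

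Dendritic-like cells of Il4 knockout tumours had higher Cxcl9. Of 7275 genes 11 were higher and 17 lower (698 at an unadjusted p under 0.05), 27 of the 28 without overlap. Cxcl9 rose from 286 to 828 CPM (log2 1.497, SE 0.17, adjusted p = 0.00191, edgeR's quasi-likelihood test), Procr, the protein C receptor gene, from 27.2 to 78.1, Dnase1l3 from 35.9 to 87.9 and the phospholipase gene Plaat3 from 64.3 to 144. Dcstamp, a cell fusion gene, fell from 149 to 41.6 CPM (log2 -1.83, adjusted p = 0.0249), the C-type lectin genes Clec4n from 134 to 50.1 and Clec4a2 from 54.7 to 20.9, and Flrt3 from 46.3 to 18.3. The NF-κB cytokine list had a median of -0.46 (adjusted p = 3.1e-07, and adjusted p = 0.281 with an estimated correlation), with 2 members lower over all genes, Il1b (3314 to 2005 CPM) and Nfkbiz, and 10 adjusted over the list alone. IL-4/STAT6-induced genes had a median of -0.70 (adjusted p = 3.9e-05, and adjusted p = 0.281 with an estimated correlation), 1 lower over all genes, and 7 lower and 1 higher adjusted over the list alone. Arg1 stood at 151 and 73.8 CPM against 2719 and 1216 in macrophage-like cells, and free macrophage RNA was not tested in dendritic-like sums, so lower macrophage lists are not read as changes of dendritic cells. Interferon-γ-induced genes had a median of 0.63 (adjusted p = 2.8e-17, and adjusted p = 0.281 with an estimated correlation), with 3 members higher over all genes, among them Psmb9 at 0.69, and 9 adjusted over the list alone. Epcam, an epithelial marker also found on some dendritic cells, fell from 87.5 to 45.8 CPM. Whether this RNA came from dendritic or from cancer cells was not tested. Without controls 1, 2 or 3, 5, 93 and 11 genes passed, and without knockout libraries 1, 2 or 3, 12, 7 and 10. At resolution 2 the class was a different set of cells, since it took in a cluster of 1098 cells with median UMIs at 0.394 of their libraries' median and macrophage markers detected in 55.5%, and 0 genes passed there (969 at an unadjusted p under 0.05). Adding F8 control 4 left 0 genes (444 at an unadjusted p under 0.05), doublets kept gave 9, the stricter cell filter 7, and a fit without a low-count filter called 249. The F8 control 4 value lay within or beyond the knockout range for 11 of the 28 genes. It lay between the groups for 10 and within or beyond the control range for 7.

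Epithelial/mesothelial-like cells, which include the edited cancer cells, showed the largest interferon-γ and MHC class II medians of the 11 classes tested. Of 13014 genes 64 were higher and 30 lower (1859 at an unadjusted p under 0.05), without overlap for all 94. Iigp1, an interferon-inducible GTPase gene, rose from 17.5 ± 7.50 to 90.4 ± 18.6 CPM (log2 2.39, SE 0.30, adjusted p = 0.0171, edgeR's quasi-likelihood test), the related genes Tgtp2 from 17.9 to 65.7 and Gbp2 from 84.6 to 304. The long non-coding RNA gene Snhg18 (ENSMUSG00000096956, chromosome 15, 32240565 to 32244662, minus strand) rose from 10.1 ± 2.72 to 42.7 ± 2.55 CPM (log2 2.12, adjusted p = 0.00304). Ccz1 (ENSMUSG00000029617, chromosome 5, 143987909 to 144014877, minus strand), whose product activates the endosomal GTPase Rab7, fell from 191 ± 47.3 to 43.3 ± 2.49 CPM (log2 -2.16, SE 0.15, adjusted p = 0.00160). The hypoxia-induced gene Ankrd37 fell from 121 to 63.2 CPM and the calcium-binding protein gene S100a4 from 324 to 172. Arg1 was also called lower (29.8 to 10.6 CPM), but macrophage RNA at the level of C1qa, C1qb and C1qc in these sums gave 104.6% of its fall. Of 19 interferon-γ-induced genes 18 lay above 0 (median 1.27, adjusted p = 4.0e-56, and adjusted p = 0.132 with an estimated correlation), with 12 higher over all genes and 18 adjusted over the list alone. MHC class II genes had a median of 1.43 (adjusted p = 5.5e-16, and adjusted p = 0.132 with an estimated correlation), with 3 of 13 higher over all genes, among them the class II transactivator gene Ciita (1.87) and H2-DMa (1.66), and 8 higher and 1 lower adjusted over the list alone. MHC class I genes had a median of 0.63 (adjusted p = 1.7e-27, and adjusted p = 0.152 with an estimated correlation), with 5 of 14 over all genes, led by Psmb8 at 1.32 and Psmb9 at 1.11, and all 14 adjusted over the list alone. Cell cycle genes had a median of 0.36 (adjusted p = 6.1e-14, and adjusted p = 0.214 with an estimated correlation), Ccnb1 and Birc5 passing over all genes and 13 of 20 adjusted over the list alone. Glycolysis and hypoxia genes had a median of -0.34 (adjusted p = 1.2e-10, and adjusted p = 0.334 with an estimated correlation), with the angiogenic factor gene Vegfa alone passing over all genes (405 to 323 CPM) and 12 of 16 adjusted over the list alone. The 6 T cell marker genes had a median of 2.05 in this class (adjusted p = 4.55e-12, and adjusted p = 0.132 with an estimated correlation), with none passing over all genes and 6 adjusted over the list alone, and Cd3g stood at 0.342 CPM in controls and 1.56 in knockout libraries. Cluster 6 was largest in all BM1 controls and in knockout library 2, and cluster 3 in knockout libraries 1 and 3 and in F8 control 4. Without control 1, 2 or 3, 59, 168 and 35 genes passed, and without knockout library 1, 2 or 3, 17, 28 and 20. Adding F8 control 4 left 7, DESeq2 called 349 and a fit without a low-count filter 314. F8 control 4 lay within or beyond the knockout range for 41 of the 94. It lay between the groups for 40 and within or beyond the control range for 13. Its values of Ccz1 (216 CPM) and Snhg18 (3.83) lay on the control side. Those of Tgtp2 (57.7), Ankrd37 (58.2), S100a4 (174) and Arg1 (1.90) lay within or beyond the knockout range. Those of Iigp1 (51.4) and Gbp2 (223) lay between the groups.

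The remaining classes gave few or no genes. In endothelial-like cells the complement inhibitor gene Serping1 (36.8 to 194 CPM), Stmn2 (30.6 to 144) and the epoxide hydrolase gene Ephx1 (42.5 to 158) rose (adjusted p = 0.0381 each, edgeR's quasi-likelihood test; 616 of 6567 genes at an unadjusted p under 0.05). There, cluster 27 (led by Clec4g and Stab2) was largest in controls 1 and 2 and cluster 24 (led by Ly6c1 and Cxcl12) in all other BM1 libraries. Without control 3, 96 genes passed. Without controls 1 or 2 or knockout libraries 1, 2 or 3, with F8 control 4 added, with doublets kept or at either other resolution 0 passed (297 to 727 at an unadjusted p under 0.05), whereas DESeq2 called 41 and a fit without a low-count filter 402. In erythroid-like cells 3 genes rose and 4 fell of 3629, among them Cxcl9 (16.8 to 62.5 CPM), Arg1 (265 to 87.4), F13a1 (log2 -1.82) and Pf4 (220 to 83.5), and leaving out control 2 or 3 gave 10 and 1 genes, leaving out knockout library 2 or 3 gave 0 and 2, and leaving out control 1 gave 4. DESeq2 called 11 there, and 80 passed without a low-count filter. In plasma-like cells 2 immunoglobulin variable segments rose (597 of 8132 genes at an unadjusted p under 0.05), and leaving out control 1 or knockout library 1 or 3 gave 6, 7 and 7 genes. DESeq2 called 31 there and a fit without a low-count filter 30. In B-like, T-like, fibroblast-like and neutrophil-like cells 0 genes passed edgeR's quasi-likelihood test, with 824, 864, 535 and 310 at an unadjusted p under 0.05 and 36, 29, 33 and 19 called by DESeq2. Fits without a low-count filter called 257, 241, 257 and 157. Their lowest p-values belonged to Gbp2 (1.13, adjusted p = 0.0709) in B-like cells, Cxcl9 in T-like cells (29.0 and 75.9 CPM, adjusted p = 0.0640), the immunoproteasome gene Psmb9 (1.33, adjusted p = 0.196) in fibroblast-like cells and Cxcl9 (2.58, adjusted p = 0.0581) in neutrophil-like cells. Without knockout library 2, 36 genes passed in B-like cells, without knockout library 1, 13 in fibroblast-like and 6 in neutrophil-like cells, and without knockout library 3, 15 in neutrophil-like cells, with at most 3 genes in these classes without any other library. In T-like cells 0 to 2 genes passed without any 1 library, and 9 rose with the mixed T cell and macrophage cluster included. NK-like and plasmacytoid dendritic (pDC)-like cells were too few to test, with 16 and 12 cells in the smallest library.

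Across the 11 classes, interferon-γ-induced genes and MHC class I genes were higher in all 11 by camera with its preset correlation. Their medians ran from 0.20 to 1.27 and from 0.27 to 0.79, and the lowest adjusted p = 0.132 and adjusted p = 0.143 with an estimated correlation. MHC class II genes were higher in 8 classes, cell cycle genes in 8 and oxidative phosphorylation genes in 6, and with an estimated correlation the lowest adjusted p = 0.132, adjusted p = 0.214 and adjusted p = 0.209. Red cell and platelet markers were higher by camera in 4 classes, with medians from -0.28 to 2.98 (lowest adjusted p = 0.293 with an estimated correlation). Epithelial and ID8 cancer cell markers were lower by camera in 2 of the 6 classes where they were tested (lowest adjusted p = 0.295). Glycolysis and hypoxia genes were lower in all 11 (medians -0.71 to -0.16, lowest adjusted p = 0.146 with an estimated correlation), lipid-associated genes in 10 and resident macrophage genes in 9 (adjusted p = 0.0366 each). Lower as well were NF-κB cytokine genes and myeloid chemokines in 8 each (lowest adjusted p = 0.270 and adjusted p = 0.0978 with an estimated correlation), complement genes in 6 (adjusted p = 0.162) and IL-4/STAT6-induced genes in 5 (adjusted p = 0.0554). No background of macrophage RNA was subtracted from these sums. C1qa stood at 5.07% to 12.4% of its macrophage-like level in T-like and 5.75% to 10.7% in erythroid-like cells, and macrophage-like cells were a smaller share of the knockout libraries. Lower macrophage lists in classes other than macrophage-like and monocyte-like cells are therefore not read as changes of those cells. Higher interferon and MHC lists in those classes carry the same limit. In epithelial/mesothelial-like cells macrophage RNA gave a median of 0.0386% of the rise of the called higher genes, which narrows the limit for those genes only. List members not called there, and RNA of other cell types, were not tested. The components of IL-4 and IL-13 signalling passed in none of the 10 classes where they were tested (lowest adjusted p = 0.293 with an estimated correlation). With an estimated correlation 2 of the 290 pairs passed, the lipid-associated and resident macrophage lists in erythroid-like cells (adjusted p = 0.0366 for each), and with fry 5 passed.

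**Figure D2:**
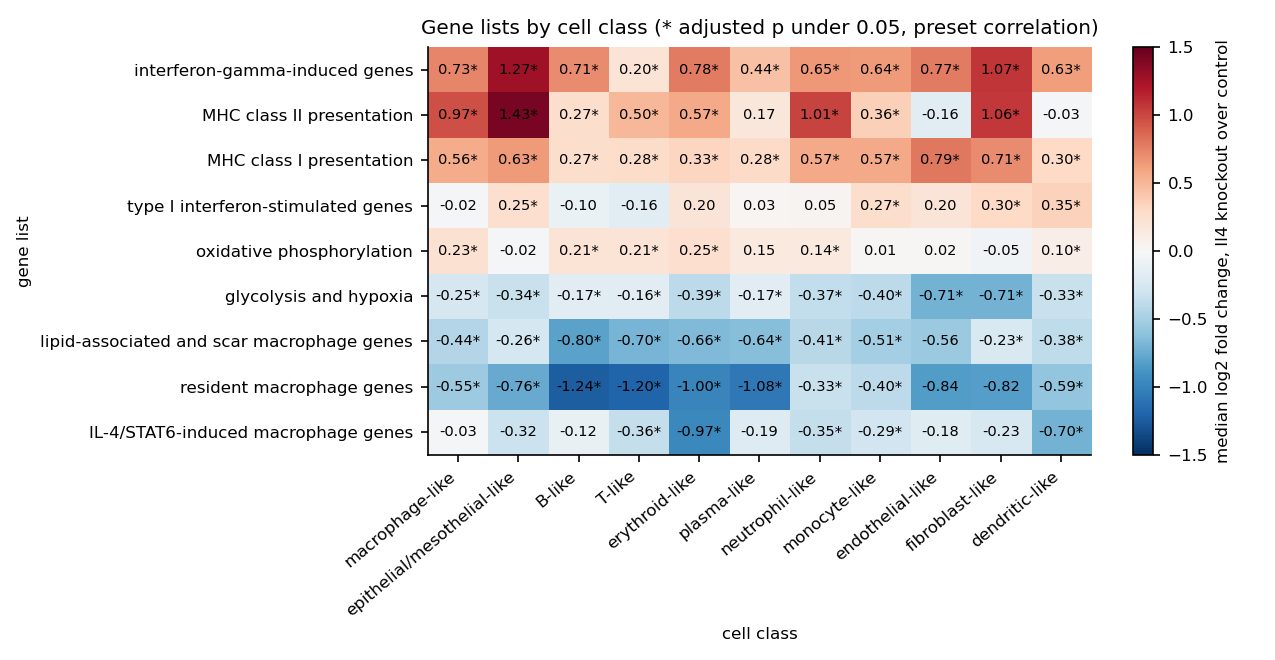
Median log2 fold change of 9 fixed gene lists (vertical axis) between 3 Il4 knockout and 3 F8 control libraries in 11 cell classes (horizontal axis), with colour and printed values giving the median and stars marking an adjusted p under 0.05 by camera with its preset correlation. Medians of interferon-γ-induced genes lay between 0.20 and 1.27 and those of glycolysis and hypoxia genes between -0.71 and -0.16, and 2 of 290 pairs passed with an estimated correlation.

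Cell class shares were compared on the same 6 libraries. Macrophage-like cells made up 40.8% ± 2.06 of kept cells in BM1 controls and 27.3% ± 4.47 in knockout libraries, monocyte-like cells 2.99% ± 0.474 and 1.78% ± 0.552, T-like cells 4.59% ± 1.25 and 9.39% ± 3.38, and pDC-like cells 0.222% ± 0.0589 and 0.725% ± 0.213. For these 4 of 13 classes the groups did not overlap (exact two-sided permutation p = 0.1, adjusted p = 0.325), and 0.1 is the smallest p that 3 libraries against 3 can give, so no share could pass this test. With edgeR on cell counts, which can pass at this size, 0 shares did, with 2 at an unadjusted p under 0.05, pDC-like (log2 1.70, adjusted p = 0.0663) and T-like cells (1.03, adjusted p = 0.292). The log2 ratios of macrophage-like and monocyte-like cells were -0.58 (adjusted p = 0.342) and -0.74 (adjusted p = 0.292). At resolution 2 the monocyte-like groups overlapped (2.497% and 1.90%, exact permutation p = 0.2). As shares of immune cells alone, macrophage-like cells made up 65.1% and 45.7% and T-like cells 7.19% and 15.7%. Shares of B-like cells (7.24% ± 2.63 and 9.71% ± 3.46, exact permutation p = 0.4), plasma-like cells (2.02% ± 1.51 and 5.52% ± 2.37, p = 0.2), NK-like cells (0.598% ± 0.522 and 1.67% ± 1.43, p = 0.3) and epithelial/mesothelial-like cells (12.8% ± 6.55 and 10.1% ± 2.98, p = 0.6) overlapped. Erythroid-like (4.84% and 5.93%), neutrophil-like (3.38% and 2.13%), endothelial-like (1.98% and 2.54%), fibroblast-like (1.60% and 1.66%) and dendritic-like cells (1.45% and 1.71%) overlapped as well. F8 control 4 had 28.6% macrophage-like, 5.96% T-like, 3.07% monocyte-like and 0.349% pDC-like cells, so its macrophage-like share lay within the knockout range. At resolution 2 (28.2%) and without cluster 5 that share lay above all 3 knockout libraries and below all 3 BM1 controls. CD45 selection and the cell filters can set these shares. Clusters left unnamed held 15.5% ± 2.95 of cells in BM1 controls and 19.8% ± 5.62 in knockout libraries, and among them a cluster with both T cell and macrophage markers held 1.27% ± 0.494 and 4.12% ± 0.953. Cluster 5, which counts as macrophage-like, held 10.2% ± 2.39 and 4.73% ± 1.38.

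**Figure D3:**
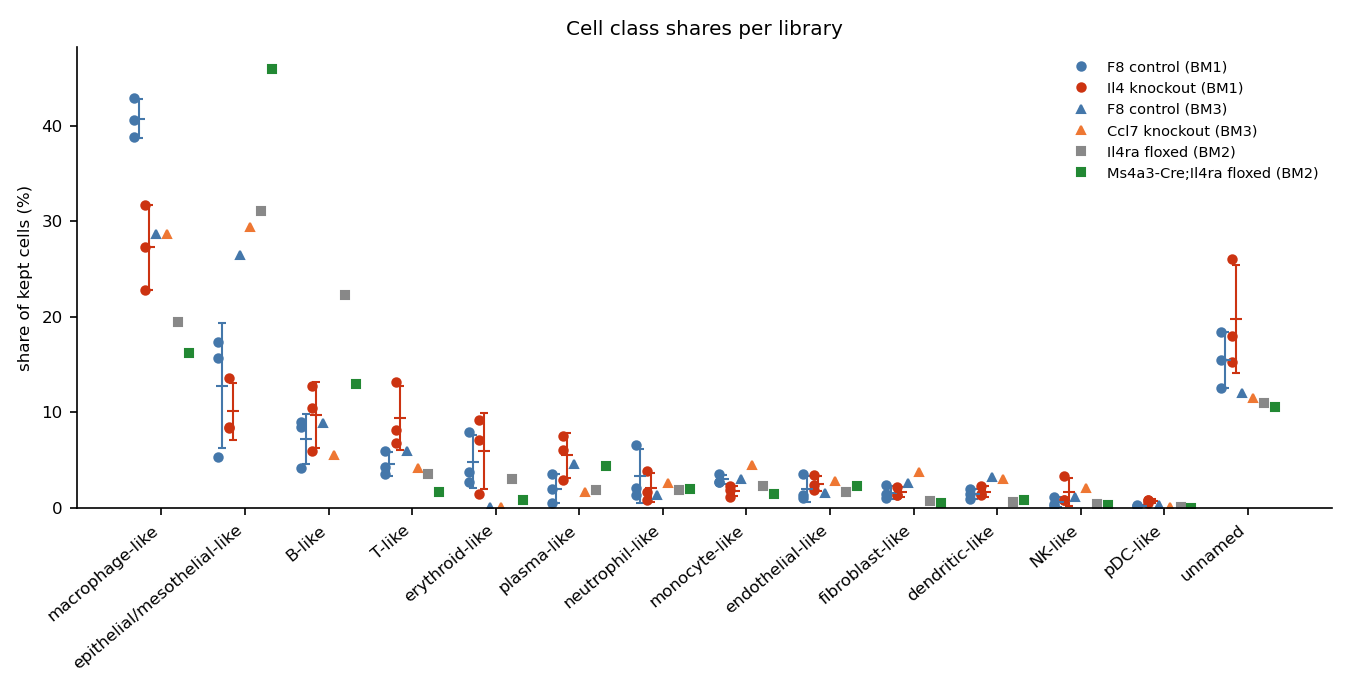
Share of kept cells (vertical axis, %) in each cell class (horizontal axis), with 1 point per library and bars giving mean ± SD for the groups of 3 libraries. Macrophage-like shares averaged 40.8% in BM1 controls and 27.3% in Il4 knockout libraries, and F8 control 4 stood at 28.6%.

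The omentum pair asked what differs when cells descending from Ms4a3-expressing progenitors lack the IL-4 receptor α chain. Macrophage-like cells of the Cre-carrying library held far less RNA of resident macrophage genes than those of the littermate. Cluster 19, with Selp and F5 of the resident list among its leading genes and macrophage markers detected in 83.7%, was left unnamed. It held 1 cell of the Cre-carrying library and 90 of the littermate, which enter neither these sums nor the macrophage-like shares. Cluster 2, led by genes such as Fcna, Cbr2, Folr2, Lyz1 and Marco, held 60 of the 957 macrophage-like cells of the Cre-carrying library and 378 of the 1481 of the littermate, so these values mix the make-up of the class with levels within its cells. With 1 library per group these values compare 2 libraries, not 2 genotypes, and no test was made. Marco, a scavenger receptor gene, stood at 41.8 CPM in the Cre-carrying library and 405 in the littermate (ratio 0.103, 0.0863 to 0.123), and the lectin gene Fcna at 88.8 and 559 CPM (0.159, 0.141 to 0.179). Lyz1, which encodes a lysozyme (0.129), the endothelin receptor gene Ednrb (0.156), the acute phase gene Saa3 (0.209), the antioxidant gene Gpx3 (0.214), the carbonyl reductase gene Cbr2 (0.230), the folate receptor gene Folr2 (0.243) and Gpnmb (0.244) were also among the 10 lowest ratios, with the immunoglobulin gene Ighg2b lowest at 0.0608. Arg1 stood at 336 and 1039 CPM (0.323, 0.303 to 0.345), Chil3 at 32.3 and 86.0 CPM, and Mrc1 at 217 and 341 CPM. Retnla had 0 counts in the Cre-carrying library and 44 in the littermate, at least 6.32-fold lower. Cxcl9 stood at 301 and 170 CPM (1.77, 1.63 to 1.93), and the ratios of Stat6, Il13ra1, Cd274, Ccl7 and Spp1 were 1.008, 1.005, 1.06, 0.718 and 0.691. The highest ratios included Zmynd15 (2.23), Lpar6 (2.07) and Rgs1 (1618 and 822 CPM, 1.97), and the pancreatic digestive enzyme genes Ctrb1 (488 and 0 counts), Cela2a and Clps were found in the Cre-carrying library, in B-like cells too. Of 2797 genes with enough counts, 8 had a ratio of at least 2 and 51 of at most 0.5.

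Among the lists in these omental macrophage-like cells, resident macrophage genes had a median log2 ratio of -1.41 (percentile 0 among 10000 expression-matched random lists), lipid-associated genes -0.54 (0) and IL-4/STAT6-induced genes -0.34 (0.02), with 7 of 21 above 0. Myeloid chemokines (-0.42) and type I interferon genes (-0.29, 0 of 18 above 0) also lay at percentile 0. MHC class II genes (0.35), cholesterol genes (0.69) and cell cycle genes (0.41, 19 of 20 above 0) lay at percentile 100, while interferon-γ-induced genes (0.07, percentile 73.6) and MHC class I genes (0.04, percentile 55.5) lay within the random range. B cell markers (-1.19, percentile 0) and red cell markers (-0.67, percentile 0.1) differed in the same sums. In epithelial/mesothelial-like cells the MHC class II genes H2-Aa (249 and 40.3 CPM, 6.17), H2-Eb1 (5.78) and Cd74 (901 and 172 CPM, 5.23) had the highest ratios and Hbb-bt (0.465), Slurp1 (0.508) and Hbb-bs (0.513) the lowest. The largest epithelial/mesothelial-like cluster was cluster 18 in the littermate and cluster 3 in the Cre-carrying library. Macrophage-like cells were 16.2% (15.3 to 17.2) of kept cells in the Cre-carrying library and 19.5% (18.6 to 20.4) in the littermate, B-like cells 13.0% (12.2 to 13.9) and 22.3% (21.4 to 23.3), epithelial/mesothelial-like cells 46.0% (44.7 to 47.2) and 31.1% (30.03 to 32.1), and plasma-like cells 4.34% (3.83 to 4.89) and 1.90% (1.60 to 2.23). The macrophage-like share of the Cre-carrying library was 17.8% and 12.2% at resolutions 0.5 and 2, its epithelial/mesothelial-like share 49.7% at resolution 2, and the IL-4/STAT6 median -0.61 at resolution 2.

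Genes called in the Il4 knockout macrophage-like cells were then followed in the omentum pair, which shares no library with them. Genes are not replicates, so the percentiles describe these libraries only. Cluster 1, led by Cx3cr1 and Cxcl9, made up 53.0% of macrophage-like cells in the Cre-carrying library and 39.7% in the littermate. Make-up of the class was therefore not separated from levels within its cells. Of the 37 higher genes 35 had enough counts, 27 of them above 0, with a median log2 ratio of 0.24 (percentile 99.99; random lists -0.0948 to 0.148). Of the 11 lower genes 10 had enough counts, none above 0, with a median of -0.51 (percentile 0.06; random lists -0.243 to 0.312), and -0.85 at resolution 2. In epithelial/mesothelial-like cells the 64 higher genes had a median of 0.21 (percentile 100) with 48 above 0, and the 30 lower genes -0.04 (percentile 37.3). Ccz1 stood at 114 CPM in each library.

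The Ccl7 knockout library asked the same of cancer cells lacking the monocyte-attracting chemokine Ccl7. It held 211 macrophage-like cells against 2135 in F8 control 4, and no test was made. Its macrophage-like cells had 9.50 CPM of H2-M2 against 54.5 (ratio 0.174), and lower Zmynd15 (0.353), Ly6a (0.438), the lectin gene Mgl2 (63.9 and 138 CPM, 0.464) and the B cell survival factor gene Tnfsf13b (0.483). Hbb-bs, a haemoglobin gene, had the lowest ratio at 0.0535. The histone gene Hist1h2ap (258 and 77.2 CPM, 3.34) and Gpx3 (2.69) were among the highest. Ccl7 itself stood at 476 and 714 CPM (0.666, 0.638 to 0.695), Arg1 at 2836 and 1937 (1.46), Cxcl9 at 340 and 348 (0.977, 0.927 to 1.03) and Chil3 at 24.8 and 4.47 (5.55). In the BM1 controls the ranges were 7.63 to 14.9 CPM for H2-M2, 107 to 260 for Hist1h2ap, 358 to 544 for Ccl7, 2287 to 3583 for Arg1, 172 to 236 for Cxcl9 and 28.5 to 163 for Chil3. All of these but Cxcl9 and Chil3 thus placed the Ccl7 knockout value inside the BM1 control range. Of 2700 genes 15 had a ratio of at least 2 and 7 of at most 0.5.

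MHC class II genes had a median log2 ratio of -0.41 against F8 control 4 (percentile 0) but 0.33 against the mean of the BM1 controls, and interferon-γ-induced genes 0.07 (percentile 44.0) and 0.37. IL-4/STAT6-induced genes had 0.33 (percentile 99.3) and 0.06, type I interferon genes -0.35 (percentile 0) and MHC class I genes -0.25 (percentile 0.16). Epithelial (2.10), neutrophil (2.01) and fibroblast markers (1.78) were higher and red cell markers (-3.29) lower in the same macrophage-like sums. In epithelial/mesothelial-like cells Mal2, a membrane trafficking gene (65.4 and 3.18 CPM, 20.6), the cornified envelope gene Sprr1a (1355 and 184 CPM, 7.36) and Rcan2 (6.99) had the highest ratios, and Ncam1 (0.0902), Slpi (0.110) and Rspo1 (0.123) the lowest. Ccz1 stood at 46.6 and 216 CPM (0.216, 0.201 to 0.231). Macrophage-like cells were 28.6% (25.4 to 32.0) and 28.6% (27.6 to 29.7) of kept cells in the Ccl7 knockout library and F8 control 4, but 38.8% to 42.9% in BM1 controls. At resolution 2 these shares were 29.4% and 28.2%, and 32.5% to 37.7% in BM1 controls. The shallow cluster 5 held a mean of 10.2% of cells in BM1 controls, 0.136% in the Ccl7 knockout library and 0.107% in F8 control 4. Epithelial/mesothelial-like cells were 29.4% (26.2 to 32.9) and 26.5% (25.5 to 27.5), and 5.32% to 17.4% in BM1 controls.

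The genes called in Il4 knockout macrophage-like cells turned with the control used for the Ccl7 knockout library. The 37 higher genes had a median log2 ratio of -0.20 against F8 control 4 (percentile 0, 15 above 0) and 0.47 against the mean of the BM1 controls (percentile 100, 31 above 0). The 11 lower genes had 0.33 (percentile 89.1, 10 above 0) and -0.33 (percentile 1.96, 1 above 0). The BM1 controls entered both comparisons in the second case. For the 100 genes of lowest p in each direction the medians were 0.41 and -0.34, whereas unchanged groups simulated against shared controls gave 0.15 (0.08 to 0.21 over 50 simulations) and -0.12 (-0.19 to -0.06), and part of the excess may come from the shared controls, which are too few to split.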

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

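The tests of free RNA in T-like and erythroid-like cells and in the lower epithelial/mesothelial-like genes, of the Ccl7 knockout line and of splits of the libraries by called genes were chosen after the results were seen.

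In Il4 knockout tumours interferon-γ-induced genes were higher in macrophage-like cells (median log2 0.73), and the dendritic markers Clec9a and Xcr1 rose in the same sums. Dendritic cells counted as macrophage-like would bring their share of these genes, and the share implied by Xcr1, Clec9a and Flt3 was 2.13% to 4.02% in BM1 controls and 6.48% to 9.68% in knockout libraries. That share gave a median of 9.60% of the rise of the 6 called list members (7.16% to 30.3%), which argues against it as the whole cause. Without cluster 5, the macrophage-like cluster of lowest depth, the list's median was 0.76, 103.1% of its value with them, which argues against shallow cells. Chance, mouse-to-mouse differences and the position of F8 control 4, with Cxcl9 at 348 CPM between the groups, stay open. So does the make-up of the class, which was not tested. At resolution 2, cluster 9 was led by Cxcl9, Dnase1l3 and Slamf8. It held 175, 180 and 121 cells in BM1 controls, 462, 330 and 440 in knockout libraries and 418 in F8 control 4. A response of macrophages to loss of Il4 in the cancer cells therefore remains a hypothesis. With 1 line per edit it cannot be told apart from a difference between lines.

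Cxcl9 rose and Arg1 fell in erythroid-like sums, and T-like sums had 29.0 and 75.9 CPM of Cxcl9 without passing. Free macrophage RNA would keep the ratio of Cxcl9 to Arg1 found in macrophage-like cells of the same library. Over 6 libraries and both classes the largest departure was 1.06 on the log2 scale, and C1qa stood at 5.07% to 12.4% of its macrophage-like level in T-like and 5.75% to 10.7% in erythroid-like cells. These values are consistent with free RNA as the source, a test that could have come out otherwise. No biological explanation was tested.

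In epithelial/mesothelial-like cells 64 genes rose and 30 fell. Free macrophage RNA at the level set by C1qa, C1qb and C1qc (0.599% to 1.38% of UMIs) gave a median of 0.0386% of the rises (-1.01% to 5.80%, 0 of 64 over 50%) and 0.624% of the falls (0.0294% to 104.6%), which argues against it for all but 4 falls, Arg1 (104.6%), Gpnmb (92.3%), F13a1 (87.0%) and Alox5ap (67.4%), of which it gave over 50%, and a largest chromosome median of -0.027 (chromosome 18, lowest adjusted p = 0.97) argues against whole-chromosome gain or loss. A difference between edited lines that the Ccl7 knockout line shares may account for some of the lower genes, which had a median log2 ratio of -0.36 in the Ccl7 knockout library against F8 control 4 (percentile 0), but not for the higher ones by that control (-0.23, percentile 0). Against BM1 controls the medians were -1.13 and 0.46, where the controls that chose the genes enter again and unchanged groups simulated for 100 genes each way gave -0.11 and 0.11, so part of these values may come from the shared controls, and the explanation stays open for the higher genes. The knockout of Il4 itself stays open for the genes that free RNA does not account for, since with 1 line per edit the design gives no test of the knockout apart from the line.

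With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As many genes as the real split were called by 1 of 10 splits in macrophage-like cells (48, highest other 0), epithelial/mesothelial-like (94, 0), monocyte-like (71, 5), dendritic-like (28, 1) and endothelial-like cells (3, 0), by 3 in plasma-like cells (2, 2) and by 10 in B-like (0, 2), T-like (0, 2), fibroblast-like (0, 2) and neutrophil-like cells (0, 3). In erythroid-like cells 2 splits did (7, 18), and the split with 18 genes set controls 1 and 3 with knockout library 2 against the rest, which may point to a structure of the samples other than the groups, a reading that was not tested. For lists, 9 of 10 splits gave as many in macrophage-like cells (13, highest other 22), so list counts there do not set the real split apart. As many lists came from 1 split in B-like (18, 14), T-like (18, 14), erythroid-like (15, 12), monocyte-like (15, 10) and neutrophil-like cells (13, 11), 2 in dendritic-like (14, 14) and plasma-like (11, 12), 4 in endothelial-like (8, 14) and 5 in epithelial/mesothelial-like (10, 14) and fibroblast-like cells (9, 13).

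The Il4 knockout effect differed from that in macrophage-like cells, by an interaction term in edgeR, for 58 genes in dendritic-like cells, of which 5 were higher there and 53 lower, among them H2-Eb1 (-1.29), H2-Aa (-1.21) and Dcstamp (-1.67). It differed for 33 genes in endothelial-like cells (Lcn2 3.62, Ephx1 2.11), for 23 in monocyte-like cells (Ace 3.18, Ccl17 -2.60, Cd74 -0.68) and for 22 in neutrophil-like cells (Elane 7.62, Mmp9 2.05, Saa3 -1.56). It differed for 10 genes in B-like cells (H2-Eb1 -0.89, Ciita -1.26), 8 in T-like cells (Klrk1 -1.92, Hopx 1.10), 8 in epithelial/mesothelial-like cells (Ccz1 -2.08, Emp1 1.23), 7 in plasma-like cells (Rasgrp1 -2.34), 4 in erythroid-like cells, all of them immunoglobulin variable segments, and 3 in fibroblast-like cells (Ctsk 3.22, Gpx3 1.65). These genes were chosen after their values were seen. The 53 genes lower in dendritic-like cells included the dendritic markers Clec9a (-1.84) and Xcr1 (-1.36), which rose in the macrophage-like sums. Dendritic cells counted as macrophage-like were therefore not separated from a differing effect in that comparison. In endothelial-like cells, cluster 27 made up 74.3% and 61.4% of the class in controls 1 and 2. Cluster 24 made up 63.1% to 87.2% in control 3 and the knockout libraries. Make-up of the class was not separated from a differing effect there, nor in the other classes.

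Among the 4 F8 controls, 3 of 45 values tried had a library far from the others, where chance picks out about 1 in 20 groups. B-like cells made up 4.22% of control 1 and 8.52% to 8.99% of the others. Neutrophil-like cells made up 6.63% of control 2 and 1.37% to 2.12% of the others. H2-M2 stood at 54.5 CPM in macrophage-like cells of control 4 and 7.63 to 14.9 in the others. In cells left out of the comparisons, the cluster with T cell and macrophage markers held a mean of 4.12% of cells in Il4 knockout libraries, the lowest of them 3.09%, and at most 1.83% in any of the 4 controls. This cluster held 3.53% of the Ccl7 knockout library, 0.685% of the littermate and 0.20% of the Cre-carrying library. Its median UMIs stood at 2.62 of its libraries' median, and whether it holds doublets was not tested.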

How the results depend on the processing

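Alternatives without the shallow cluster 5, with left-out clusters and with the mixed T cell and macrophage cluster were chosen after the data were seen. Of the named genes under settings other than leaving out a library, 503 values kept direction and side of the threshold, 149 kept direction without passing and 38 passed newly. With a library left out these numbers were 263, 170 and 11. The 1 reversal was Retnla in macrophage-like cells, which did not pass, from 0.54 to -0.17 with F8 control 4 added. Of main counts, shares and pair values, 159 stayed (counts within 1.5 times, share differences of the same sign, pair values within a counting interval or the random lists' half-width), 64 moved and 4 reversed, that is, changed sign as a share difference or as a pair value of macrophage-like cells that lay outside the random lists at first, and with a library left out 96, 53 and 7. RLE normalization (38 higher, 11 lower) and thinning (37 and 12, with 44 of 48 genes shared) kept the macrophage-like count. For the values below the cause was not tested. Added or left-out libraries change the number of samples and a missing filter the number of genes tested, but whether this moved the counts was not tested either.

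DESeq2 called 310 genes in macrophage-like, 349 in epithelial/mesothelial-like, 108 in monocyte-like, 41 in endothelial-like, 36 in B-like, 33 in fibroblast-like, 31 in plasma-like, 29 in T-like, 19 in neutrophil-like and 11 in erythroid-like cells. Without a low-count filter edgeR called 201, 314, 381, 402, 257, 257, 30, 241, 157 and 80 in the same order, and 249 in dendritic-like cells. Adding F8 control 4 gave 0 in macrophage-like, monocyte-like, dendritic-like and endothelial-like cells (823, 513, 444 and 297 at an unadjusted p under 0.05) and 7 in epithelial/mesothelial-like cells. Doublets kept gave 0 in macrophage-like and endothelial-like cells, 9 in dendritic-like, 1 in B-like and 1 in T-like cells. The stricter cell filter gave 21 in macrophage-like, 7 in dendritic-like, 2 in fibroblast-like and 2 in neutrophil-like cells. Resolution 0.5 gave 15 in macrophage-like, 0 in endothelial-like and 3 in neutrophil-like cells, and resolution 2 gave 16, 0 and 3, with 0 in dendritic-like and 1 in T-like cells. Macrophage-like counts were 24 with monocyte-like cells, 24 without cluster 5 and 22 with left-out clusters, and T-like cells with the mixed cluster gave 9. With an estimated correlation 2 of 290 list pairs passed and with fry 5, and 0 and 0 in macrophage-like cells.

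The dendritic-like share difference turned from 0.258 to -0.362 percentage points at resolution 2, where the class took in cluster 23 (1098 cells, median UMIs at 0.394 of the libraries' median, macrophage markers in 55.5%) and is a different set of cells, and the fibroblast-like one to -0.0187 without cluster 5. The monocyte-like difference went from -1.20 to -0.594 at resolution 2, where the groups overlapped. Against the mean of the BM1 controls the Ccl7 knockout library differed by -12.1 points in macrophage-like share (-5.07 at resolution 2) and 16.6 in epithelial/mesothelial-like share. Its list medians against that mean were 0.33 for MHC class II (reversed), 0.37 for interferon-γ, 0.061 for IL-4/STAT6, -0.34 for lipid-associated and -0.35 for resident macrophage genes. Called genes there had 0.47 for higher and -0.33 for lower ones, each opposite in sign to its value against F8 control 4 (-0.20 and 0.33), of which the lower ones' 0.33 lay within the random lists and counts as moved. At resolutions 0.5 and 2 the Cre-carrying library's macrophage-like share was 17.8% and 12.2%, and at resolution 2 its epithelial/mesothelial-like share 49.7%, its IL-4/STAT6 median -0.61 and its median of lower genes -0.85. Its resident median was -1.21 at resolution 0.5.

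Leaving out each library in turn gave 0 to 175 genes in macrophage-like, 12 to 54 in monocyte-like, 5 to 93 in dendritic-like, 17 to 168 in epithelial/mesothelial-like, 0 to 96 in endothelial-like, 0 to 10 in erythroid-like, 2 to 7 in plasma-like, 0 to 36 in B-like, 0 to 2 in T-like, 0 to 13 in fibroblast-like and 1 to 15 in neutrophil-like cells, and 125 to 161 list pairs (12 to 16 in macrophage-like cells). Share differences in points ran from -15.7 to -11.2 for macrophage-like, -1.46 to -0.908 for monocyte-like, 2.89 to 6.11 for T-like, 0.431 to 0.625 for pDC-like, 2.48 to 4.80 for plasma-like, 0.939 to 4.34 for B-like, 0.244 to 1.497 for NK-like, 0.0933 to 1.34 for endothelial-like, -6.43 to -0.380 for epithelial/mesothelial-like, -0.534 to 3.31 for erythroid-like, -0.235 to 0.457 for fibroblast-like, -2.25 to 0.379 for neutrophil-like and -0.0611 to 0.517 for dendritic-like cells. No monocyte-like class existed at resolution 0.5, and erythroid-like cells were too few with F8 control 4 added or the stricter filter. No paired analysis was possible because the labels give no replicate numbers that groups share. Depth limits Il4, with at most 38 UMIs in a library, and the Ccl7 knockout library, with 737 cells.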

Other observations

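T-like cells had a higher cell cycle list in Il4 knockout tumours (median log2 0.54, adjusted p = 3.4e-10 by camera, and adjusted p = 0.293 with an estimated correlation), while 0 single genes passed edgeR's quasi-likelihood test (864 at an unadjusted p under 0.05, 29 called by DESeq2). The cytotoxicity list, higher by camera in 2 of the 3 classes where it was tested, had a median of 0.11 in T-like cells. With an estimated correlation 0 lists passed in T-like cells. Monocyte genes had a median of 0.05 there although their mean was -0.41 and their test lower (adjusted p = 0.0130, and adjusted p = 0.293 with an estimated correlation). Ifng, the gene of interferon-γ, stood at 157 ± 91.8 CPM in T-like cells of controls and 144 ± 18.0 in those of knockout libraries, at 67.3 ± 46.1 and 112 ± 60.3 CPM in NK-like cells, and at 4.00 ± 3.496 and 9.36 ± 4.21 CPM over all kept cells. In T-like cells Ifng did not pass (log2 -0.06, adjusted p = 0.978), and the NK-like and all-cell values were not tested. In neutrophil-like cells the granule genes had a median of 0.89 (adjusted p = 6.4e-08 by camera, and adjusted p = 0.308 with an estimated correlation), with the calprotectin genes S100a8 and S100a9 at 1.23 and 0.89 without passing.

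Ccz1 had the lowest p of the genes called lower in epithelial/mesothelial-like cells, and its values followed the edited line more than the tumour site. It stood at 233, 140, 200 and 216 CPM in F8 controls 1 to 4 of the diaphragm and 114 CPM in each omental library, which also held F8 control cells, but at 46.2, 41.7 and 42.0 CPM in Il4 knockout libraries and 46.6 CPM in the Ccl7 knockout library. No test of the line apart from the knockout can be made with 1 line per edit. In the omentum pair, plasma-like cells of the Cre-carrying library and of the littermate had 1564 and 10.6 CPM of the immunoglobulin constant gene Ighg3.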
